A study of Chlamydomonas reinhardtii with 2 samples.

How the data were processed

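Poly-A selected, randomly fragmented RNA was sequenced as 36-base single-end reads from 1 wild-type sample and 1 sor1 sample, per the labels. Per the deposited readme, the authors aligned reads with SOAP (version not given in the sources used here), first at full length with up to 2 mismatches and no indels. Reads that failed were then trimmed base by base at either end, to no fewer than 21 bases, until they matched perfectly. The deposited files list counts of uniquely aligned reads, without normalization, for each alignment start position and alignment length; strand and gene are not columns of these files. The readme names the v.3.1 assembly for the alignment and the v4 assembly for the positions, counted from the first base of chromosome 1 through the scaffolds. It does not say whether the files differ in this. The wild-type runs held 3904806 and 3996001 reads, of which 9.96% (exact binomial 95% interval 9.93 to 9.99) and 9.57% (9.54 to 9.60) had been trimmed. The sor1 run held 9005690 reads, with 6.52% (6.51 to 6.54) trimmed. Intervals and floors cover counting error only, since repeated amplification products cannot be told from independent molecules.

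Taken at equal positions, the files did not correspond. The last position was 118213979 in the wild-type files and 112305237 in the sor1 file. Over bins of 20000 bases the correlation of log counts was 0.99 between the wild-type runs and 0.18 between either run and sor1; bins are not independent replicates. Positions were not converted with a chain file, and the assembly of each file is left open. Each library's positions were kept in its own frame. Windows were matched only by the fine pattern of read starts: the log of full-length read starts plus 1, minus its moving mean over 61 bases. Each sor1 window of 2000 bases with at least 1000 reads that was not yet paired was searched over the whole wild-type frame in both orientations, and accepted at a similarity of at least 0.3 and 1.4 times that of the next best place. From each accepted window, neighbours with at least 100 reads were searched within 30000 bases of the carried offset, at a similarity of at least 0.2. A walk ended after 30 misses in a row. Windows of identical offset up to 100000 bases apart were joined. Any stretch between them was filled in by that shared offset, without a match of its own pattern. At each end 5% of the agreeing signal was trimmed, and intervals under 200 bases were left out. These settings were set after the files were seen, from the success of the pairing and its checks and not from differences between the libraries.

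The pairing was checked in 3 ways. Of 8352 windows with enough reads, 3452 were matched, and of 1349 windows with at least 1000 reads, 1270. Of 866 matched windows lying between 2 windows of 1 offset, 856 had that same offset (98.8%). When 1726 matched windows were searched in the wrong orientation at the same place, 12 were accepted (0.7%). For a simulation, full-length sor1 reads of the first 24000000 bases were split into 2 parts. The part that stood in for the wild type was cut into shuffled and reversed pieces. In it, 100.0% of paired bases were correct and 75.6% of reads were in paired intervals. No wild-type reads were used and every base was in both frames. Differences between assemblies or library preparations were therefore not simulated, and these rates may not hold for the real comparison. There, 0.13% of 771 unchanged segments were counted as 2-fold apart. Of segments simulated at 2-fold, 4-fold and 8-fold, 64.0% of 25, 100.0% of 19 and 100.0% of 18 were counted as 2-fold apart; segments simulated at 2-fold lie at the threshold itself. Of the 200 segments changed in the simulation, 62 were in paired intervals; the others were not compared.

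The unit planned before the data were examined was the gene. As the files hold positions, the unit became the transcribed segment, read starts at most 200 bases apart, with at least 50 reads summed over both libraries. These 4714 of 20089 segments held 99.4% of the paired reads and had a median span of 1017 bases. Counts were scaled to the total in paired intervals, 7047515 for sor1 and 6237514 for the wild type, and 0.5 was added to each before the log2 ratio. Folds in the text are ratios of scaled counts. The 95% interval of a ratio is the exact Clopper-Pearson interval conditional on the summed count. Segments at least 2-fold apart were described by size, without a test across genotypes. Named segments were, by a rule fixed before the data were examined for the case without gene names, the 2 higher with the largest lower bound and the 2 lower with the smallest upper bound. They also had to be at least 2-fold apart in the same direction against each wild-type run.

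The other scalings were the median of ratios and TMM factors from edgeR 4.0.16 in R 4.3.3, which were computed on the segment counts; both moved the log2 ratios by 0.24. Alternatives also changed the count minimum, pseudocount, wild-type run, depth, alignment lengths, joining distance, interval ends and the library whose windows started the pairing. The other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The 33 gene lists fixed before the data were examined, the transcript of the mutated gene and a planned promoter comparison are not analysed here. The files do not pair positions with gene names, the reference table names 0 of its 17742 genes by a symbol other than the locus tag, and no genome was used here.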

Results

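Transcripts of the green alga Chlamydomonas reinhardtii were measured by sequencing of poly-A selected RNA in 2 samples, the wild-type strain 4A+ and the sor1 mutant. The mutant came from a search for cells that tolerate singlet oxygen, an excited form of oxygen that arises at illuminated chlorophyll. Both strains grew on acetate-containing TAP medium at 25 °C under 100 µmol photons m-2 s-1, with 12 h of light per day, and cells were harvested 6 h into the light period. The comparison asked how the transcriptome of the mutant differed from that of its parent strain under these growth conditions. The wild-type sample was deposited as 2 sequencing runs with 3904806 and 3996001 uniquely aligned reads, and the sor1 sample as 1 run with 9005690. The labels speak of 3 biological replicates but give 1 sample per genotype and do not say whether material was pooled, so no replicate check was possible and no p-value is given. Intervals are exact 95% intervals that cover counting error only.

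The files give read starts by position, with no gene names, and the wild-type and sor1 files lie in different coordinate frames. Windows of the 2 frames were therefore matched by their patterns of read starts, and 3452 windows of 2000 bases matched. Stretches between matched windows of identical offset up to 100000 bases apart were filled in without a match of their own. This gave 1691 paired intervals over 18.9 Mb, most of it filled. These intervals held 78.26% of the sor1 reads (exact binomial 95% interval 78.23 to 78.28) and 78.95% of the wild-type reads (78.92 to 78.98). Of the intervals, 999 ran in the same orientation in both frames and 692 were reversed. Read starts at most 200 bases apart were joined into transcribed segments, which may hold part of a gene or more than 1 gene, on either strand. All positions below are those of the sor1 file, and the gene at each is not analysed here.

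**Figure D1:**
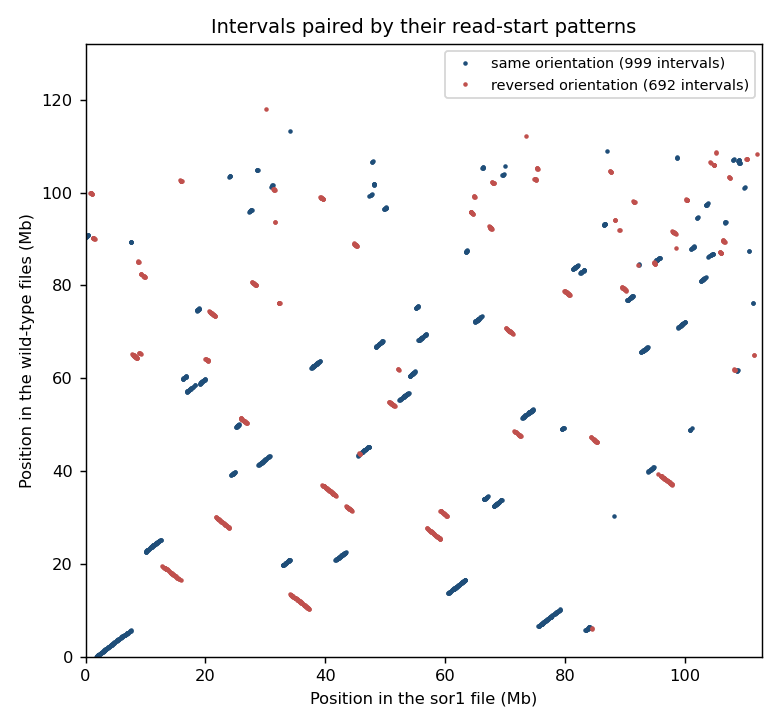
Midpoints of the 1691 paired intervals, with the position in the sor1 file on the x axis and the position in the wild-type files on the y axis, both in Mb. Blue points are the 999 intervals in the same orientation and red points the 692 reversed ones; neighbouring intervals line up in slanted runs.

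In the paired intervals, 1191 of 4714 transcribed segments (25.3%) had at least 2-fold more reads in the sor1 library, and 487 (10.3%) had at least 2-fold fewer. The other 3036 segments lay within 2-fold. At least 4-fold differences were found in 455 segments with more reads in sor1 and 67 with fewer, and at least 16-fold differences in 62 and 5. The median segment lay 0.24 above 0 on the log2 scale (SD over segments 1.28). Relative to that median, as also with TMM scaling, 951 segments were higher and 721 lower, so the share of higher segments among those 2-fold apart was 71.0% under scaling to total reads and 56.9% relative to the median. Relative to the median, 365 segments were at least 4-fold higher and 116 at least 4-fold lower, and 49 and 5 were at least 16-fold apart. Against each wild-type run taken alone, 1074 segments were at least 2-fold higher in both comparisons and 456 lower. The counting interval lay wholly beyond 2-fold for 860 higher and 330 lower segments. The counts depended on how reads were counted and on the unit. They were 498 higher and 190 lower when each start position was counted once, and 2383 and 707 in fixed bins of 1000 bases. Windows entered the pairing by their sor1 reads and by the likeness of the 2 patterns, and filled stretches by the windows around them. These shares therefore describe the paired intervals only. Pairing started from wild-type windows gave 1080 higher and 491 lower segments, and 65 and 10 at least 16-fold apart.

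The 2 wild-type runs measured the error between sequencing runs of 1 sample. Of 3948 segments with at least 50 wild-type reads, 2 were 2-fold apart between the runs, and the SD of their log2 ratio was 0.183. Their counts differed by no more than sampling noise, with a chi-square per degree of freedom of 1.006, so the runs were summed and counted as 1 sample. Between sor1 and wild type the same quantity was 266.2, and the counting interval of the ratio excluded 1 for 81.2% of segments. That contrast compares these libraries, not the genotypes, since culture-to-culture variation was not measured. Differences from library preparation or from the 2 coordinate frames were not measured either.

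**Figure D2:**
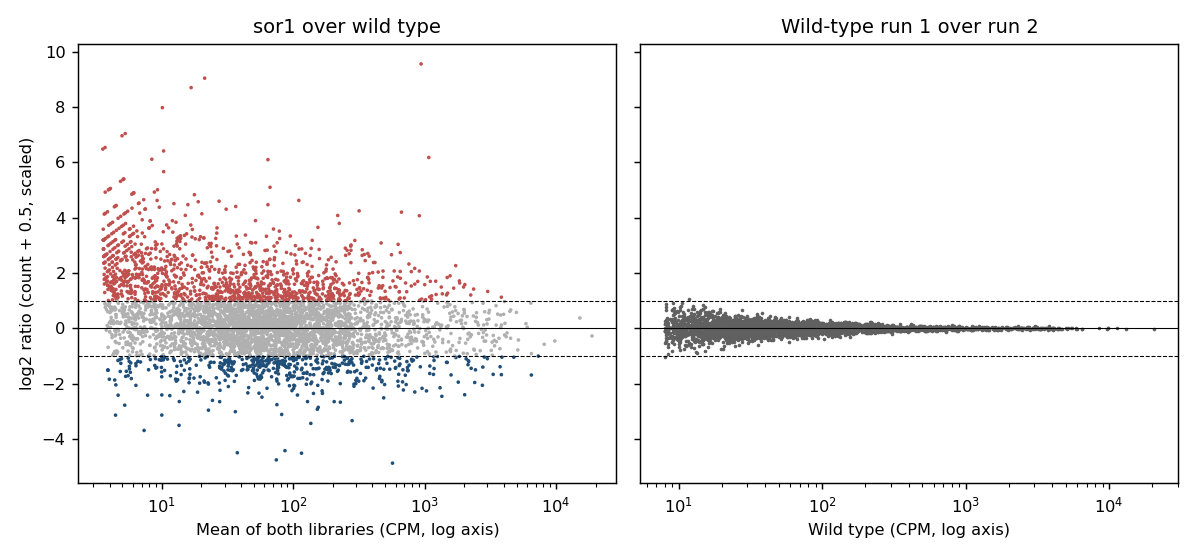
Log2 ratio of scaled read counts of each segment (y axis) against its level in CPM, counts scaled to the reads of the library in paired intervals (x axis, log scale), for sor1 over wild type on the left and wild-type run 1 over run 2 on the right. Dashed lines mark 2-fold; red points are the 1191 segments higher in sor1 and blue points the 487 lower, while 2 of 3948 segments lay outside the lines between the runs.

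The segment with the largest bound on its difference lay at positions 16793231 to 16793907, spanning 677 bases. It had 13214 reads in the sor1 library and 15 in the wild type, 780-fold more (interval 472.5 to 1393), or 661-fold relative to the median segment. The wild-type reads numbered 3 in run 1 and 12 in run 2. The segment lay in a filled stretch between the 2 matched windows of its paired interval, and its own window was not matched. Its place in the wild-type frame therefore rests on the offset shared by those windows. Only uniquely aligned reads are in the files, and whether this or any other segment is unique in both frames is not known here. Most of the reads of both libraries started in the same short part of it. A segment 624 bases further on, in the same paired interval, had 5864 sor1 reads and 4375 wild-type reads, a log2 ratio of 0.25. A short cluster of starts 302 bases before it had 142 sor1 reads and 0 wild-type reads. The levels of the segment itself were 1870 CPM in sor1 and 2.4 CPM in the wild type.

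The other segment named among those higher lay at 106728719 to 106729706, with 298 sor1 reads at 209 start positions over 988 bases and 0 wild-type reads in either run. Against the 3 counts that a count of 0 allows over both runs together, it was at least 87.9-fold higher in sor1, or at least 74.6-fold relative to the median segment, before counting error in the sor1 reads. The lower bound of the exact counting interval was 71.1-fold. Its closest neighbours with at least 50 reads were also higher in sor1, with log2 ratios of 1.61 before it and 1.84 after it. They lay 1187 and 542 bases away, and the one before it had 46 sor1 and 13 wild-type reads. Segments with fewer reads lay in between and were not compared. The named segment also lay in a filled stretch between the 2 matched windows of its paired interval, and its own window was not matched. In all, 7 of the 4714 segments had 0 wild-type reads, with 50 to 298 reads in sor1. No count of segments without sor1 reads is set against this, because windows entered the pairing by their sor1 reads. With the pairing started from wild-type windows, 8 segments had 0 wild-type reads and 3 had 0 sor1 reads.

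Among the segments with fewer reads in the mutant, the one with the firmest difference lay at 11011554 to 11012858. It had 6864 wild-type reads and 265 sor1 reads, 29.3-fold fewer in sor1 (interval 25.9 to 33.2), or 34.5-fold relative to the median. This segment ended at the trimmed edge of its paired interval, where its wild-type reads were densest, so its full extent and the stretch after it were not compared. The next lay at 91145631 to 91146631, with 893 wild-type and 37 sor1 reads, 27.3-fold fewer (19.6 to 39.0), or 32.1-fold relative to the median. Its closest neighbours with at least 50 reads had log2 ratios of -0.07 before it and -0.58 after it. The segment before these in the same paired interval, at 91140221 to 91141927 and chosen after its values were seen, had 1030 wild-type reads and 54 sor1 reads, a log2 ratio of -4.42. When each was split at the middle of its sor1 reads, both parts of the first segment were lower, at log2 ratios of -5.11 and -4.56, while the parts of the other differed, at -5.54 and -2.47.

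**Figure D3:**
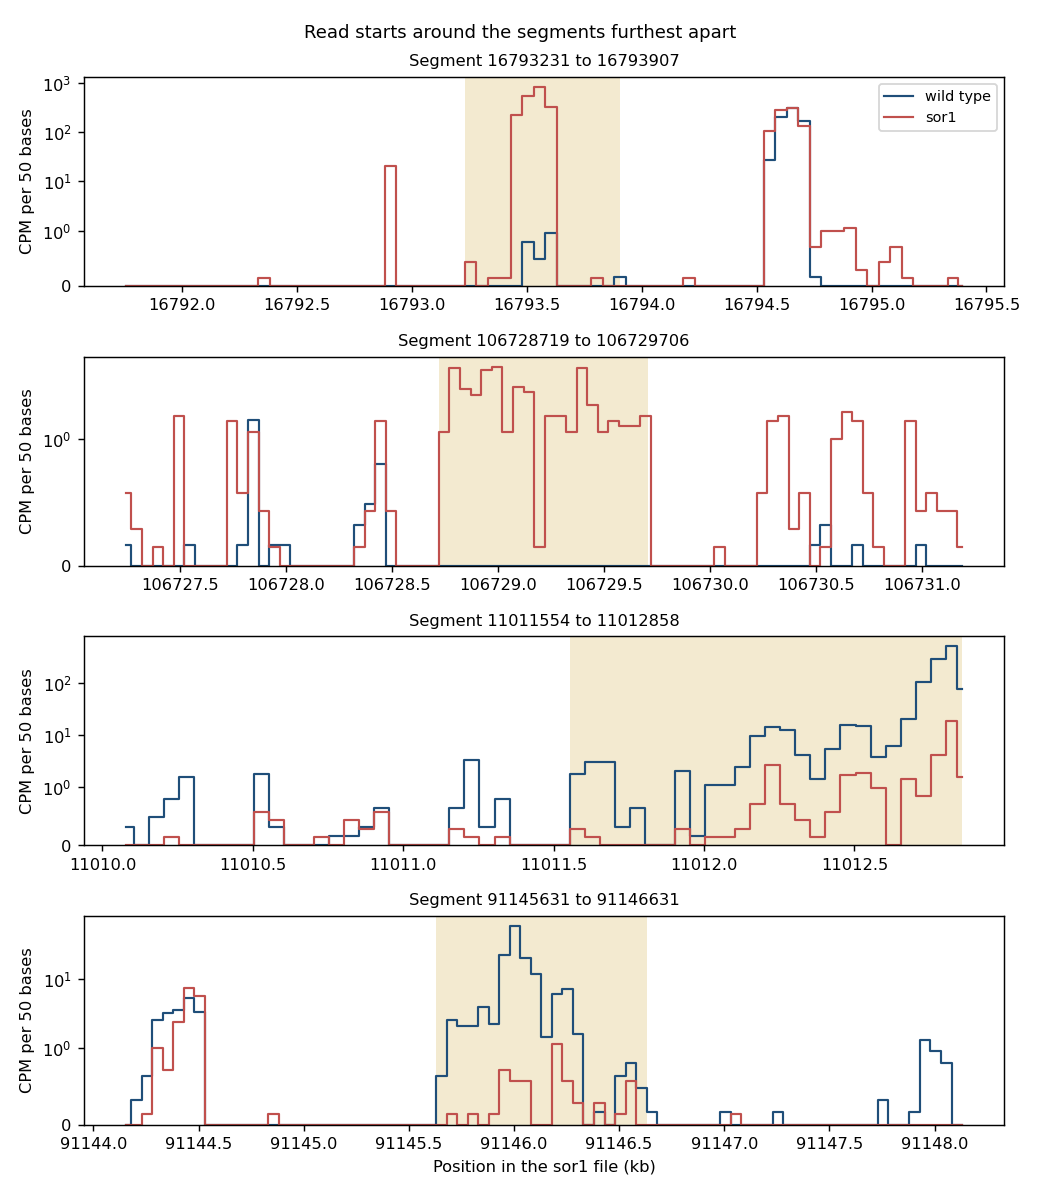
Read starts per 50 bases, in CPM on a log axis that is linear below 1, around the 4 segments named, with the position in the sor1 file in kb on the x axis. Red lines are the sor1 library, blue lines the wild type, and shading marks the segment; the upper panels show 13214 against 15 and 298 against 0 reads, the lower ones 265 against 6864 and 37 against 893.

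The direction of difference varied with transcript level. The segments were put into 3 classes of nearly equal size by mean level. In the lowest class, 3.5 to 29.9 CPM, 614 were higher and 112 lower in sor1, so that 84.6% of those 2-fold apart were higher. In the middle class the counts were 303 and 161, and in the highest class, from 99.8 CPM up, they were 274 and 214, or 56.1% higher. Relative to the median segment, the share of higher segments was 76.6% in the lowest class, 46.8% in the middle and 38.8% in the highest, so the direction in the middle and highest classes turned with the scaling. Segments higher in sor1 held 20.51% of the paired sor1 reads (exact binomial 95% interval 20.48 to 20.54) and 6.60% of the wild-type reads (6.58 to 6.62). Segments lower in sor1 held 8.06% (8.04 to 8.08) and 21.9% (21.87 to 21.94). Both sets were picked from these same counts for being 2-fold apart, so the direction of these shares was fixed by the choice. The intervals do not allow for that choice.

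In the paired intervals, the most abundant transcribed segments were largely shared. Pairing itself asked for like patterns in both libraries, so stretches abundant in only 1 of them could be left out. Of the 100 segments with most reads in each library, 65 were in both lists. Of the 135 segments in either list, 16 were at least 2-fold higher in sor1 and 27 lower, or 13 and 39 relative to the median segment. The top 100 segments took 39.44% of the paired wild-type reads (39.40 to 39.48) and 35.25% of the sor1 reads (35.21 to 35.28). The segment with most wild-type reads had 20540 CPM in the wild type and 17010 CPM in sor1, 1.21-fold lower (counting interval 1.198 to 1.217). The segment with most sor1 reads had 13200 CPM in the wild type and 17140 CPM in sor1, 1.30-fold higher (1.287 to 1.31). Both folds are under scaling to total reads, at log2 ratios of -0.27 and 0.38. Relative to the median segment each log2 ratio is lower by 0.24, a shift that the counting intervals do not cover.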

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

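The tests of the first segment's start positions, of the 50-base steps with wild-type reads and of the split lower segments were chosen after related results were seen. The tests by background subtraction and by splitting the higher segments were chosen after the data were seen but before their own results, and after its first value was seen the split was moved from the middle of all reads to the middle of the sor1 reads that had been set down.

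Reads outside the paired intervals carry signal that the comparison does not use: 21.7% of the sor1 reads and 21.1% of the wild-type reads. In the sor1 file, 76 windows of 2000 bases each held at least 1000 such reads, 284845 in all, and the window with most held 31372. Of 51 gaps whose flanking paired intervals bracket a stretch of the wild-type frame, 29 had at least 2-fold more sor1 reads and 2 at least 2-fold fewer, or 27 and 2 per base. These gaps spanned 888 to 278174 bases of the sor1 file. The median log2 ratio was 1.25, or 1.26 per base, scaled to all reads of each library. The brackets covered 3196792 bases in the sor1 frame and 3253810 in the wild-type frame, were picked by their sor1 reads, and were not shown to hold the same sequence. The bracket furthest apart, singled out after its values were seen, lay at 16018410 to 16030073 of the sor1 file and had 16629 sor1 reads over 11664 bases, against 133 wild-type reads over 8806 bases.

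The first pattern was the excess of higher over lower segments, 71.0% of those 2-fold apart. Subtracting the read density far from segments, which was 0.493 CPM per kb in sor1 and 0.222 in the wild type, left 70.2%. Background at that density thus does not account for the excess, but background closer to segments was not measured. Thinning the sor1 library to the wild-type total left 70.05%. Counts were already scaled to totals, so thinning could move the share little and does not decide on library size. In the class of highest level, 1 of 3 of nearly equal size, the share was 56.1%, between the bounds set for and against wild-type reads being more concentrated on abundant segments. That explanation therefore cannot be told apart from a difference between genotypes. Relative to the median segment the share was 56.9% over all segments, 38.8% in the highest class and 76.6% in the lowest. Under that scaling both classes met the bounds set for this explanation, so the outcome of the test turned with the scaling. The genotype stays untested, with 1 library each.

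The next pattern was the near-empty wild-type segment at 16793231 to 16793907. Wild-type reads may have been dropped there because the stretch is not unique in the assembly used for that file. At the 13 start positions that hold its 15 wild-type reads, sor1 had 1240 reads, 73.2-fold more (counting interval 44.2 to 131). The positions were picked for holding a wild-type read, which lowers this ratio, and the interval does not allow for that choice. With about 1 wild-type read per position, the wild-type reads could be stray ones that a mismatch or trimming made unique. The explanation by dropped reads therefore stays open. A difference of culture or strain history, or of genotype, also stays open and was not tested.

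The last pattern was the set of higher segments as a whole, since a stretch unique in only 1 assembly could appear higher or lower without any change in RNA. Of 724 higher segments with at least 200 reads, 59.4% were 2-fold higher in both parts when split at the middle of their sor1 reads, just under the 60% set as what this explanation needs, so it stays open as a part of the pattern; with the split at the middle of all reads the share was 56.1%. Of 417 lower segments, 38.4% were 2-fold lower in both parts, or 51.3% with the split at the middle of all reads, and segments close to 2-fold also fail this test by counting error. When only 50-base steps with wild-type reads were counted, 89.0% of the 724 stayed at least 2-fold higher. A single wild-type read kept a step in, and the steps held a median of 97.6% of the sor1 reads of a segment, so this restriction left the explanation open too.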

How the results depend on the processing

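The alternatives that changed the joining of read starts, the intervals used, repeated starts, the split segments, the background, the trimming of interval ends and the library that started the pairing were chosen after the data were seen; the others were set beforehand. Higher segments outnumbered lower ones under every alternative run. Both scalings to the bulk of segments, the median of ratios and TMM, moved the share of higher segments among those 2-fold apart from 71.0% to 56.9%, by lowering every ratio alike. Without a count minimum, 11020 segments were higher and 3229 lower (77.3% higher), since segments with few reads then entered; with a minimum of 200 there were 724 higher segments, and the share was 63.5%. Joining starts within 100 bases gave a share of 74.6%. Joining within 400 bases gave 734 higher segments and 64.5%, and fixed bins of 1000 bases gave 2383 and 77.1%. These alternatives change how many units are counted. Intervals of 2 or more matched windows, the only ones that can hold filled stretches, gave 1071 higher and 344 lower among 3821 segments, or 75.7%. All intervals gave 1191 and 487 among 4714, so the count of lower segments fell more than that of higher ones. Intervals of a single matched window were not counted on their own, so the excess of higher segments was not shown there. Trimming 20% of the signal at interval ends gave 68.6%, and pairing started from wild-type windows 68.7%. The cause of these shifts was not tested. Counting each start position once gave 498 higher and 190 lower segments among 4486 with at least 50; the cause was not tested. Asking for both parts of a split segment to be 2-fold apart left 184 lower segments and a share of 81.6% with the split at the middle of the sor1 reads. With the split at the middle of all reads it left 787 higher and 250 lower segments, a share of 75.9%. Counts and share moved little with a pseudocount of 5, either wild-type run alone, the thinned sor1 library, full-length alignments alone or subtracted background, at 1130 to 1190 higher and 465 to 505 lower. Between the wild-type runs, 2 segments were 2-fold apart at a minimum of 50 reads, 5670 without a minimum and 0 at a minimum of 200, where counting error sets the number. The 4 named segments kept their direction under each scaling, run and pseudocount tried. This is no independent check, since the naming rule required it for the runs and the scalings moved log2 ratios by only 0.24. For the first higher one the log2 ratio was 9.56, or 10.69 and 8.89 against the runs taken alone, since it rests on 15 wild-type reads; for the one with 0 wild-type reads a pseudocount of 5 gave 5.75, so that the fitted ratio is no bound. The alternatives set beforehand for gene lists were not run, as no list member was matched. No paired analysis was possible because each genotype has 1 library, and no library could be left out. Thinning the sor1 library to the wild-type total left 1132 higher and 484 lower segments.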

Other observations

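The test of distance between neighbours was set down before its result was seen. The shuffles of runs and the stretches named here were chosen after their values were seen.

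In the paired intervals, 227 runs of 2 or more successive counted segments were all at least 2-fold higher in sor1, and 25 runs were all lower. In 1000 shuffles of the calls over all counted segments, the central 95% ran from 139 to 175 higher runs and from 21 to 39 lower runs, so the higher runs outnumbered the shuffles and the lower ones did not. Runs of at least 3 segments numbered 82 and 4, against 20 to 39 and 0 to 6 in the shuffles. Parts of 1 transcript were not told from separate genes in these counts. The shuffles also did not keep the level of a segment. The class of lowest level held 614 of the 1191 higher segments and 112 of the 487 lower ones. The excess of higher runs was therefore not told from an effect of level. The run with most segments, 9, lay at 80361755 to 80376203 of the sor1 file, over 14449 bases, with 3140 sor1 and 767 wild-type reads summed over its segments. The longest run of lower segments, 4 in number, lay at 21870394 to 21872705, with 103 sor1 and 1963 wild-type reads. As each segment of a run was picked for being 2-fold apart, no fold is given for the sums. A higher segment at 94874435 to 94874917 had 14938 sor1 reads and 182 wild-type reads, at levels of 2120 and 29.2 CPM.

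A hypothesis was that changed genes are grouped along the genome beyond the parts of 1 transcript. Across segments, which are not independent replicates, the Pearson correlation of log2 ratios between successive segments was 0.212 at 200 to 1000 bases, over 951 pairs, against a central 95% of -0.062 to 0.062 in 1000 shuffles of the ratios. It was 0.081 at 1000 to 5000 bases, over 1067 pairs, against -0.058 to 0.055, and 0.059 at 5000 to 20000 bases, over 956 pairs, against -0.064 to 0.061. The correlations at the shorter distances thus lay above the shuffles, and the one at the longest lay just inside them, so grouping at that distance was not detected and is not excluded. At the shorter distances the correlation may come from exons of 1 transcript that were split into several segments, which was not tested. The shuffles of ratios, taken over all segments, did not keep level either.

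At an equal depth of 2000000 reads in paired intervals, the sor1 library covered 628768 distinct start positions and the wild type 508394.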
